A study of Homo sapiens with 12 samples.

How the data were processed

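Total RNA of 12 samples, 2 per line and arm, was labelled with biotin and hybridised to Illumina bead arrays, per the labels. The deposited table of scanner output holds the average bead signal (intensity) per probe on a linear scale, per the file headers, with no normalisation between arrays seen in its values. The detection p-value of each probe and array was deposited beside it, per the file headers. The authors' deposited matrix holds intensity values on a linear scale with the same quantiles on all 12 arrays, from a lowest value of 1.67 to a highest of 23494. The software behind these steps is not given in the sources used here. Its ranks followed those of the same array's scanner signals, with a correlation of 1 on every array.

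The scanner signals of 47323 probes were corrected and normalised with limma 3.58.1 in R 4.3.3 (neqc: background estimated from the detection p-values, offset 16, quantile normalisation, log2). A probe was kept where its detection p-value was under 0.05 on at least 2 of the 12 arrays, which left 24187 probes. Of the 47323 probes, 30113 had 1 gene symbol in the probe table, 8 had several and 17202 had no symbol there. The most strongly expressed probe stood for each gene, which gave 13135 genes. Symbols were compared with the reference gene table, where 30074 matched by gene identifier and 0 changed.

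A group-means model with 6 groups was fitted with limma (lmFit, eBayes), with 6 residual and 7.65 prior degrees of freedom. Contrasts were knockdown minus control in each line, their mean, their differences between lines, and control against control. The difference between lines was also tested with a moderated F test. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, for the 42 of 44 lists with at least 5 measured genes (877 of 1065 list genes). Adjustment ran over the lists of each contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

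The groups, lists, tests and the rule for naming genes were fixed before the data were examined. The rule names the 12 largest rises and falls past the threshold with 1 direction in all lines for the mean of 3 lines, 6 of each per line, the members of the monocarboxylate transporter list, up to 4 members of each list, and the 8 genes with the lowest interaction p. The genes of the marker plot and of the control array comparison were chosen after their values were seen.

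The procedure was tested on simulated data built from the 13135 genes with 200 changed. For the mean of 3 lines 62.5% of 1.5-fold, 95.0% of 2-fold and 100% of 4-fold changes were called, and 1.78% of calls were wrong. In single lines 50.0% to 56.25% of 2-fold changes were called, and 7.29% of calls were wrong in MiaPaca2, over the 5% aimed at, 1.12% in Capan-2 and 0% in PL45. For an effect in 1 line, the F test called 7.5% of 2-fold and 80.0% of 4-fold changes. A list of 37 genes shifted by 0.25 passed camera with adjusted p = 1.07e-25, and the same list with no shift had adjusted p = 0.956. The simulated noise was drawn independently for each gene, so this run cannot show whether the preset correlation suits the real data.

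Alternatives changed the background correction, the scaling, the filter, the choice of probe, the variance model, the pairing and the arrays used, and one used the authors' values. Probes with no symbol entered no comparison of genes.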

Results

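The study lowered the lactate exporter MCT4 (the product of SLC16A3) by RNA interference in 3 human pancreatic cancer cell lines, MiaPaca2, Capan-2 and PL45. RNA was taken 72 h after transfection from cells given the SLC16A3 reagent (knockdown) or a non-specific one (control). Each line and arm has 2 arrays, so 12 arrays form 6 groups, all on 1 slide. The median signal per array ranged from 111 to 129 and the mean from 377 to 513, and 18076 to 19753 of 47323 probes were detected (38.2% to 41.7%). A total of 13135 named genes were tested, and the number of arrays limits the precision. The labels do not say that replicates come from separate cultures, so the p-values measure only the spread between these samples. Line names below follow the labels, and PL45 stands for the arrays labelled PL45. These resemble the MiaPaca2 arrays (below), so the mean of 3 lines may rest on fewer than 3 separate lines.

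The target came first. The probe table used here names 0 probes for SLC16A3, so its level is not analysed here and the knockdown labels cannot be checked through it. The changes below are differences between cells given the SLC16A3 reagent and the non-specific one. Loss of MCT4 and other effects of the reagent cannot be told apart. Among its relatives, 10 members of the list of monocarboxylate transporters and their chaperones were measured, and 4 of them passed in the mean of the 3 lines by limma. SLC16A10, which carries aromatic amino acids, fell by 0.93 ± 0.12 on the log2 scale (SE, limma adjusted p = 0.000161), SLC16A5 fell by 0.84 ± 0.11 (adjusted p = 0.000173) and SLC16A14 fell by 0.42 ± 0.10 (adjusted p = 0.00951). SLC16A9, a carnitine and creatine carrier, rose by 0.42 ± 0.11 (limma adjusted p = 0.0215). The log2 difference of BSG, the chaperone of MCT4, was -0.01 ± 0.15 (limma adjusted p = 0.986). The same 1 rise and 3 falls passed when adjusted over the list alone. In Capan-2 SLC16A10 and SLC16A14 did not fall, with low log2 levels of 4.74 and 4.49 in control and 4.82 and 4.71 in knockdown. SLC16A5 went from 11.12 to 10.69 there and SLC16A9 from 5.71 to 5.98, in the direction of the mean.

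Which genes differ between knockdown and control across the lines? The largest changes in the mean of 3 lines included rises of CCND2, CCN1, CCN2 and HMOX1 and falls of SMCO4, TFAM and IFITM1. CCND2, a G1 cyclin, rose by 1.69 ± 0.12 (log2, SE, limma adjusted p = 2.07e-06), the matrix proteins CCN1 and CCN2 by 1.68 ± 0.13 and 1.57 ± 0.10, and HMOX1, the heme-degrading stress enzyme, by 1.61 ± 0.11 (limma adjusted p = 2.08e-06). TFAM, which packages and transcribes mitochondrial DNA, fell by 1.82 ± 0.14 (limma adjusted p = 3.7e-06). IFITM1, an interferon-induced membrane protein, fell by 1.71 ± 0.14 (limma adjusted p = 4.52e-06). SMCO4, a small membrane protein, fell by 2.04 ± 0.11 (limma adjusted p = 4.85e-07), the largest fall among genes with 1 direction in all 3 lines.

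By limma, 2034 of 13135 genes passed (adjusted p under 0.05), 916 higher and 1118 lower, of which 20 rose and 100 fell at least 2-fold. Of the 916 higher genes 699, and of the 1118 lower genes 794, had 1 direction in all 3 lines. The rest moved against the mean in at least 1 line. The other largest rises with 1 direction in all 3 lines were SH2D5, TRMT61A (a tRNA methyltransferase), CERS1 (ceramide synthesis), the histone gene H2BC12, KLF10, PEA15, HYAL3 and VPREB3, with log2 values from 1.19 to 1.38. The other largest falls were BRWD1, the guide RNAs SCARNA18, SCARNA23 and SCARNA16, the actin regulator CORO1C, KCTD20, NPTX1, CRISPLD2 and SNU13 (a box C/D ribonucleoprotein), with log2 values from -1.50 to -1.81. In each of these 24 genes the MiaPaca2 and PL45 differences exceeded the Capan-2 difference in size. Of the 24, 21 were detected on at least 2 of the 4 Capan-2 arrays, CCND2 and CERS1 on 0 and SCARNA23 on 1, so for those 3 the Capan-2 values lie at background. Without the 4 MiaPaca2 arrays 566 genes passed, and without the 4 PL45 arrays 544.

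**Figure D1:**
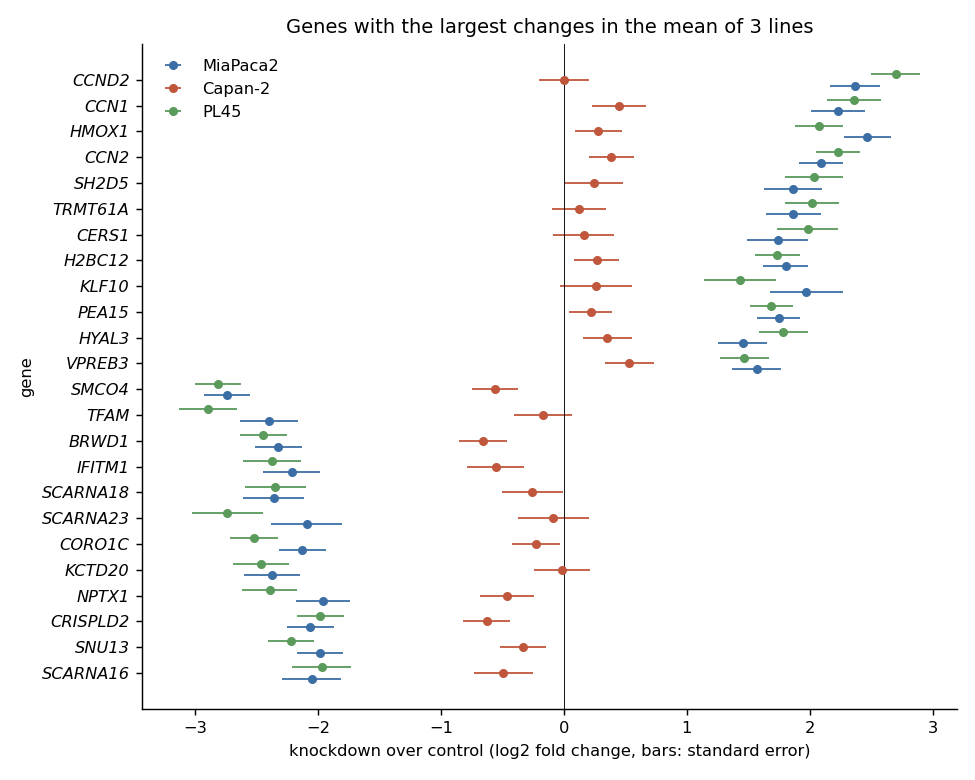
Log2 fold change of knockdown over control (horizontal axis, bars: standard error) for the 12 largest rises and 12 largest falls in the mean of 3 lines among genes with 1 direction in all lines, by line. In every gene shown the Capan-2 point lies nearer to 0 than the other lines' points, for example -0.56 for SMCO4 against -2.74 in MiaPaca2 and -2.82 in PL45. CCND2 and CERS1 were detected on 0 Capan-2 arrays.

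Energy and stress genes moved in both directions. Of the respiratory chain genes, COX7C, a subunit of complex IV, fell by 1.19 ± 0.09 (limma adjusted p = 4.75e-06) and ATP5F1B, the catalytic subunit of ATP synthase, fell by 0.91 ± 0.10 (limma adjusted p = 6.76e-05), while UQCR10 rose by 0.60 ± 0.15 (limma adjusted p = 0.0141). The mitochondrial pyruvate carriers MPC1 and MPC2 rose by 0.61 and 0.39, and PDK3 and PDHX, a kinase and a subunit of pyruvate dehydrogenase, fell by 0.66 and 0.55. Of 20 glycolysis genes, 1 rose (PFKFB3, 0.49) and 4 fell, including HK2 and PGAM1, each by 0.59 (limma, the same counts adjusted over the list alone). Glycolysis as a list had camera adjusted p = 0.0586. DDIT3, a stress transcription factor, rose by 1.09 and PPP1R15A by 0.82, while the chaperone HSPA5 fell by 0.67. BIRC5, an inhibitor of apoptosis, fell by 1.11 and the mitotic factor FOXM1 by 0.82, while CDC25A and CCNE1, which act at the G1/S step, rose by 0.75 and 0.72. These values are means of the 3 lines. In Capan-2, UQCR10, PFKFB3, CDC25A and CCNE1 were lower in knockdown and PDHX was higher, against the mean. PDHX had log2 levels of 8.31 there in control and 8.55 in knockdown. The other genes named in this paragraph kept the mean's direction in Capan-2 with smaller differences, such as ATP5F1B at 14.12 and 14.10. The G1/S genes E2F2 and CCND1 had lower levels in knockdown than in control arrays of every line. In MiaPaca2 the log2 level of E2F2 was 8.29 in control and 7.27 in knockdown, and that of CCND1 10.12 and 9.10.

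Of 42 gene lists fixed before the data were examined, 5 passed camera with a preset correlation in the mean of 3 lines. The list of type I interferon genes was lower (adjusted p = 0.00205, adjusted p = 0.357 with an estimated correlation), with 9 of 33 members lower and 1 higher (12 and 1 adjusted over the list alone). IFIT1 and BST2, which act against viral RNA and virus release, fell by 0.97 and 0.61, and ISG20 rose by 0.63. MYC targets and ribosome biogenesis genes were higher (adjusted p = 0.00205, adjusted p = 0.584 with an estimated correlation), with 6 of 31 members higher (7 adjusted over the list alone), among them MYC itself by 0.56, SRM by 0.62 and NOP16 by 0.52. Immediate early genes were higher (adjusted p = 0.00625, adjusted p = 0.436 with an estimated correlation), with 8 of 21 members higher (8 adjusted over the list alone), led by FOSB at 0.95 and DUSP5 at 0.80. The lysosome list was higher (adjusted p = 0.0133, adjusted p = 0.357 with an estimated correlation), with 11 of 37 members higher and 4 lower (13 and 4 adjusted over the list alone). SGSH and ATP6V1C1 rose by 0.81 and 0.74, and SCARB2 fell by 0.71. Epithelial markers were lower (adjusted p = 0.0326, adjusted p = 0.436 with an estimated correlation), with ELF3, KRT19, TSPAN1 and MUC1 lower by limma (4 of 25 members, 4 adjusted over the list alone) and log2 values of -1.26, -0.96, -0.90 and -0.75. In Capan-2, where the levels of these 4 are highest, the values were 0.04, -0.10, 0.07 and 0.27, and limma's F test for a difference between lines gave adjusted p = 0.00163, 0.039, 0.0261 and 0.00594. The epithelial list was lost without the PL45 arrays (camera adjusted p = 0.128) and in 4 of 12 fits that left out 1 array, and the immediate early list without the MiaPaca2 arrays (0.115). By fry the MYC list had adjusted p = 0.063.

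**Figure D2:**
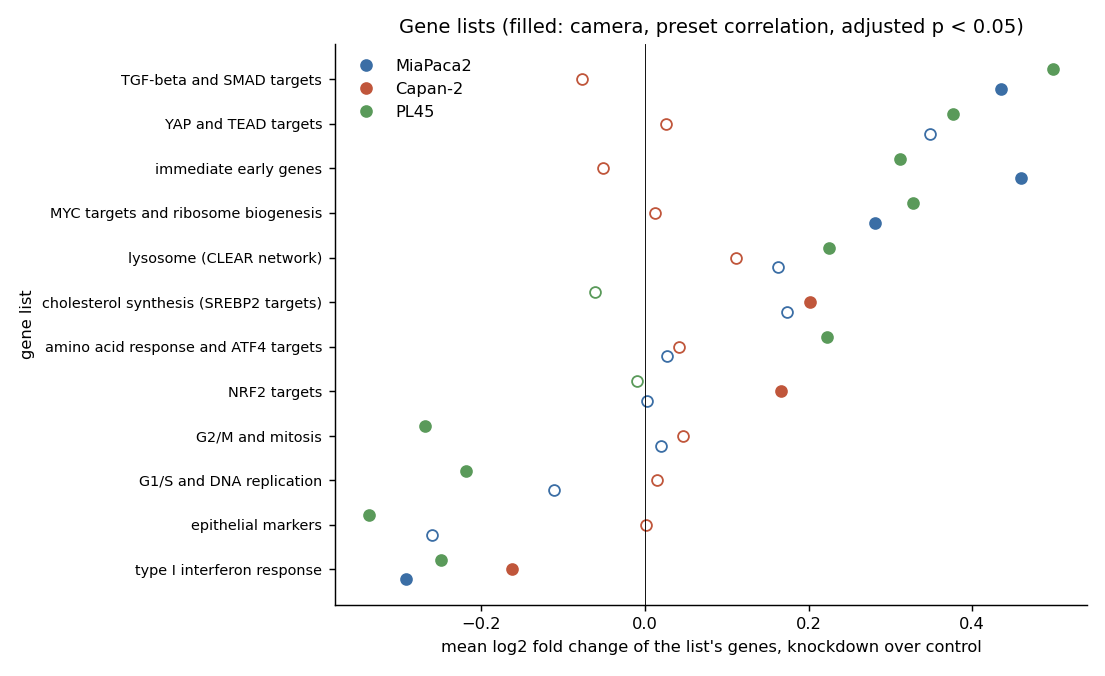
Mean log2 fold change of the genes of each list (horizontal axis) for every list that passed camera with a preset correlation in the mean of 3 lines or in a line, by line, with filled points where that line passed. The immediate early list had mean 0.46 in MiaPaca2, 0.31 in PL45 and -0.05 in Capan-2.

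In MiaPaca2, which is 1 of the 3 lines in that mean, HMOX1, CCND2, CCN1 and CCN2 were among the largest rises. HMOX1 rose by 2.47 ± 0.19 (SE, limma adjusted p = 1.96e-05), and KLF10, a TGF-beta-induced repressor, by 1.97 ± 0.30 (limma adjusted p = 0.000901). SCARNA8, which guides chemical modification of spliceosomal RNA, fell by 3.08 ± 0.28 (limma adjusted p = 3.28e-05), and CREG1, a lysosomal glycoprotein, fell by 2.51 ± 0.17 (limma adjusted p = 7.52e-06). By limma 1310 genes passed, 497 higher and 813 lower. Median scaling in place of quantile normalisation gave 211 higher and 1238 lower of 1449, and moved the median of all genes to -0.11, so the balance of small rises and falls rests on the scaling. Without MiaPaca2 knockdown replicate 2 the count was 493. Lists that passed with the preset correlation were immediate early genes (adjusted p = 0.000416), MYC targets (0.00625), type I interferon genes (0.0144) and TGF-beta targets (0.0237), the last with CCN1, CCN2, ID2 and TGFBI higher. Their adjusted p with an estimated correlation ran from 0.46 to 0.64.

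In PL45, CCND2, CCN1, CCN2 and HMOX1 were again the largest rises, and TFAM, SMCO4 and KCTD20 were among the 6 largest falls in both lines. CCND2 rose by 2.70 ± 0.20 (SE, limma adjusted p = 1.37e-05), CCN1 by 2.36 ± 0.22 (3.45e-05) and CCN2 by 2.23 ± 0.18 (1.37e-05). TFAM fell by 2.89 ± 0.24 (limma adjusted p = 1.4e-05), SMCO4 by 2.82 ± 0.19 (limma adjusted p = 9.19e-06) and, with a smaller change, ELF3, an epithelial transcription factor, by 2.22 ± 0.17 (limma adjusted p = 1.37e-05). By limma 1262 genes passed, 535 higher and 727 lower, against 639 without PL45 knockdown replicate 1. The share of higher calls moved from 42.4% to 51.5% under median scaling, where 430 rose and 405 fell. BIRC5 and FOXM1 fell by 1.67 and 1.27, and in MiaPaca2 by 1.43 and 1.07, while CDC25A and CCNE1 rose by 1.09 and 1.07 in PL45. The G2/M list passed camera lower in PL45 (adjusted p = 0.00376, adjusted p = 0.375 with an estimated correlation). So did the G1/S and DNA replication list (camera adjusted p = 0.013, adjusted p = 0.375 with an estimated correlation), against the rises of CDC25A and CCNE1. E2F2 had a log2 level of 8.92 in PL45 control and 8.18 in knockdown, and CCND1 9.82 and 9.28. The amino acid response list was higher (camera adjusted p = 0.021, adjusted p = 0.451 with an estimated correlation), with SESN2 at 1.37, CHAC1 at 1.24 and DDIT3 at 1.39. The amino acid transporter genes SLC38A2 and SLC7A1 went the other way, with log2 levels of 10.35 and 9.506 in PL45 control and 9.165 and 8.942 in knockdown. In all, 10 lists passed with the preset correlation and 0 with an estimated one (2 at an unadjusted p under 0.05), and 16 passed fry. Without PL45 knockdown replicate 1 the preset count was 4, and without PL45 control replicate 2 it was 6.

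In Capan-2, 5 genes passed. FXYD2, a regulator of the sodium pump, rose by 2.51 ± 0.22 (log2, SE, limma adjusted p = 0.000296). The proteoglycan SRGN fell by 2.36 ± 0.25 (limma adjusted p = 0.00129), the membrane protein TMEM158 by 2.08 ± 0.24 (limma adjusted p = 0.00223), SCG2, a granule protein, by 1.37 ± 0.17 (limma adjusted p = 0.00444) and HLA-DPA1, an MHC class II chain, by 1.32 ± 0.16 (limma adjusted p = 0.00444). All 4 fallen genes were higher in MiaPaca2 and PL45 controls than in Capan-2 controls, from 7.22-fold for TMEM158 to 32.8-fold for HLA-DPA1 in the lower of the 2 lines, and other genes abundant there were lower alongside without passing, such as VIM, CD74 and EMP3 at -0.87, -1.48 and -1.29. HLA-DPA1 was detected on 0 of 2 Capan-2 knockdown arrays, so background limits its fold. At an unadjusted p under 0.05, limma gave 331 higher and 334 lower genes. With no true change, 5% of the 13135 tested genes would pass at that level, about as many. In simulated data with 200 changed genes, Capan-2 had 56.25% of 2-fold changes and 100% of 4-fold changes called. With fewer changed genes the adjustment is stricter, so these shares may be lower on the real arrays. Each call was lost under at least 1 alternative, and with no background correction limma gave 0 calls and 766 genes at an unadjusted p under 0.05. The type I interferon list was lower (camera adjusted p = 0.00927, adjusted p = 0.603 with an estimated correlation), with IFITM1 at -0.55 and IFIT1 at -0.52. Cholesterol synthesis was higher (adjusted p = 0.0276, adjusted p = 0.603 with an estimated correlation), with MVK at 0.68 and SC5D at 0.63, and so were NRF2 targets (adjusted p = 0.0276, adjusted p = 0.677 with an estimated correlation), with AKR1C2 at 0.63 and GCLC at 0.56, none of these members passing alone by limma. None of the 3 lists passed with the authors' values, or by fry.

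Does the response differ between the lines? By limma's moderated F test 264 genes did. The top 8 were SERPINE2, CREG1, TRAF3IP2, CCND2, ELF3, SMCO4, SNORA79 and FXYD2 (adjusted p from 0.0012 to 0.00209). CCND2 and SNORA79 were detected on 0 Capan-2 arrays and FXYD2 on 0 MiaPaca2 or PL45 arrays, so a lack of response there is not measured. Of the 264 genes, 215 were detected on at least 2 arrays of each line. SERPINE2, a protease inhibitor of the cell surface, had log2 values of -2.09 in MiaPaca2, -2.02 in PL45 and 0.29 in Capan-2 (SE 0.17 each). TRAF3IP2, an adaptor of interleukin-17 signalling, had -2.30, -2.05 and -0.08. Between MiaPaca2 and Capan-2 279 genes differed in their effect, 98 higher and 181 lower, and between PL45 and Capan-2 255, 80 higher and 175 lower. Between MiaPaca2 and PL45, limma gave 0 genes, with 697 at an unadjusted p under 0.05, while 4 lists passed camera. The knockdown effect on the G2/M list was higher in MiaPaca2 than in PL45 (camera adjusted p = 3e-07, adjusted p = 0.549 with an estimated correlation). This is a difference of effects, and the list did not pass in MiaPaca2 itself. The F test gave 31 genes without Capan-2 control replicate 1, 47 with the authors' values, 486 with a block within lines and 640 with a block on the replicate number.

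Across genes, which are not independent replicates, the effects of MiaPaca2 and PL45 had Pearson's r = 0.72 and Spearman's rho = 0.60. They shared 262 rises and 467 falls, against 20.2 and 45 for independent lists, and 0 genes passed in opposite directions. Capan-2 had r = 0.10 with MiaPaca2 and 0.15 with PL45. Of the 729 genes called in both MiaPaca2 and PL45, Capan-2 moved in the same direction in 472 (64.8%), with a median of 0.09 against 1.01 in MiaPaca2 and 1.00 in PL45.

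**Figure D3:**
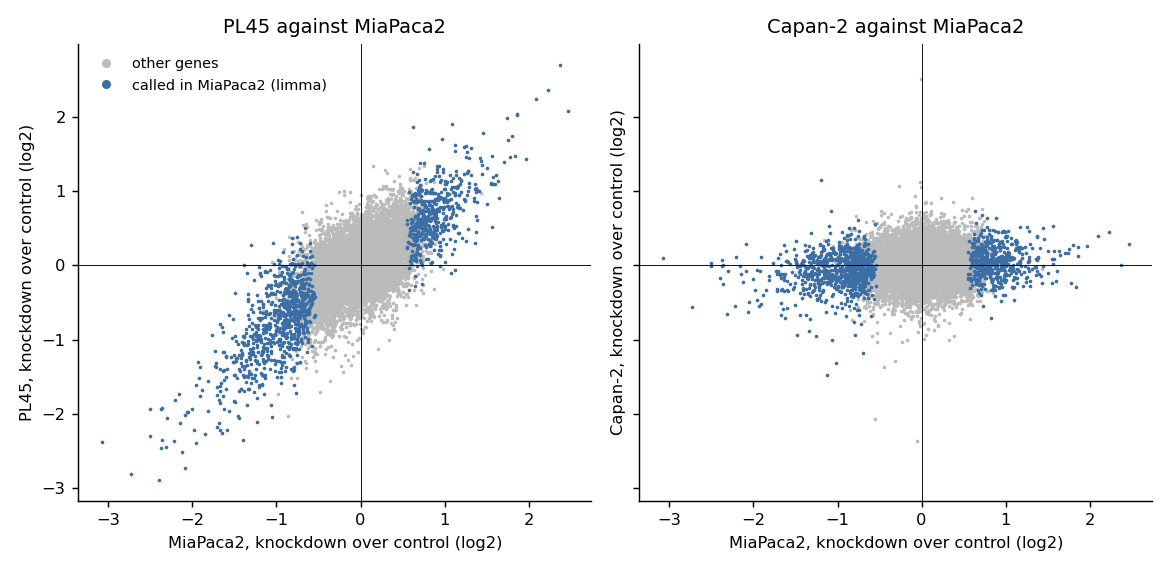
Log2 fold change of knockdown over control in PL45 (left) and Capan-2 (right) against MiaPaca2, 1 point per gene, with genes called in MiaPaca2 by limma in blue. The PL45 values follow those of MiaPaca2 (r = 0.72), and the Capan-2 values lie near 0 (r = 0.10).

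How do the lines differ before knockdown? In control arrays 6552 genes differed between MiaPaca2 and Capan-2 and 6216 between PL45 and Capan-2, but 168 between MiaPaca2 and PL45 (limma). The last count was 99 with the authors' values and 35 without PL45 control replicate 2. Epithelial genes parted them. EPCAM, an adhesion protein, had a log2 level of 13.20 ± 0.22 (SD, n = 2) in Capan-2 controls, 4.88 ± 0.24 in MiaPaca2 and 4.67 ± 0.08 in PL45, and S100P had 13.19, 4.33 and 4.34. EPCAM was detected on 1 of 2 MiaPaca2 and 0 of 2 PL45 control arrays, so the lower levels lie at background. VIM, the mesenchymal filament protein, had 14.07 in MiaPaca2, 14.08 in PL45 and 9.38 in Capan-2. The epithelial list was lower than in Capan-2 in both lines, with an estimated correlation too (adjusted p = 0.0144 in MiaPaca2 and 0.0136 in PL45). DKK1, a WNT inhibitor, had log2 levels of 9.50 in MiaPaca2 and 4.41 in PL45, where it was detected on 0 of 2 control arrays, so the difference is a lower bound. The protease gene CTSC, detected on 2 of 2 in both, had 9.46 and 5.49 (limma adjusted p = 5.71e-10 and 1.97e-08). Array correlations between MiaPaca2 and PL45 in the same arm ran from 0.978 to 0.989, against 0.988 to 0.992 within a line and arm.

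**Figure D4:**
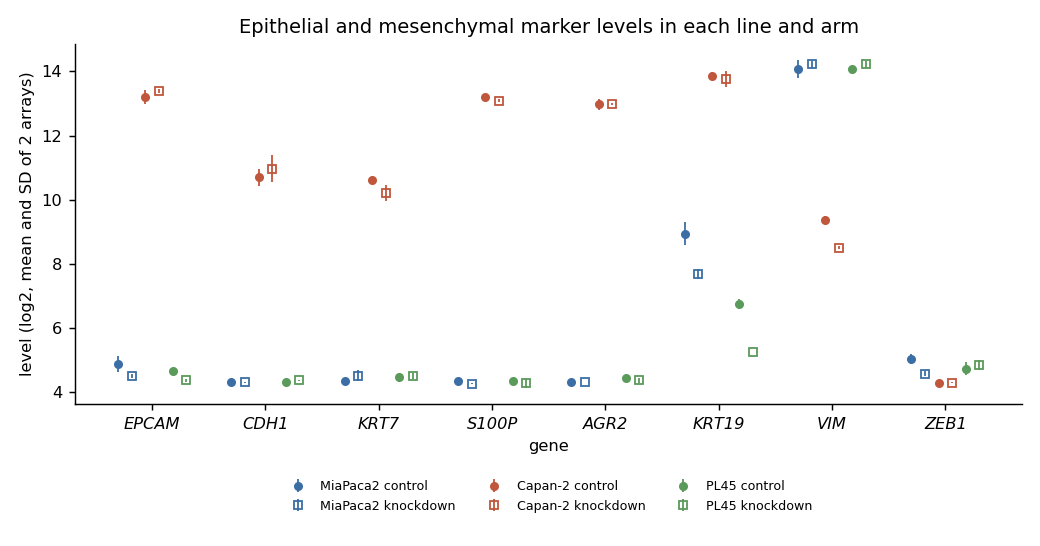
Log2 level of 8 genes (mean and SD of 2 arrays) in each line, for control (filled) and knockdown (open) arrays. EPCAM lies at 13.20 in Capan-2 controls, against 4.88 in MiaPaca2 and 4.67 in PL45.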

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

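All tests of patterns below except the comparison of splits and of dim genes were chosen only after the results were seen. The knockdown effect differed between lines in 264 genes by limma's moderated F test. The effects of MiaPaca2 and Capan-2 differed in 279 genes and 6 lists, those of PL45 and Capan-2 in 255 genes and 7 lists, and those of MiaPaca2 and PL45 in 4 lists (limma and camera, 0 of these lists with an estimated correlation). The genes with the lowest adjusted p of the F test were SERPINE2, CREG1, TRAF3IP2 and CCND2 (0.0012 each), ELF3, SMCO4 and SNORA79 (0.00163 each) and FXYD2 (0.00209). CCND2 and SNORA79 lay at background in Capan-2, and FXYD2 in MiaPaca2 and PL45. Signal outside the named genes appeared too, since 363 of 6492 probes with no symbol in the probe table passed limma for the mean of 3 lines, 179 higher and 184 lower. Of 100 drawn splits of the arrays within lines, 1 (the real one) gave as many as 2034 genes, and the highest other split gave 1917. A split that mixes the arms of a line adds the knockdown difference to the spread between replicates, which lowers its count. Chance differences between cultures are not excluded, since the labels do not say that replicates come from separate cultures. The splits that gave most of the other counts kept the MiaPaca2 and PL45 arms and mixed or exchanged Capan-2, so the count rests on those 2 lines. The split by replicate number was not among those drawn, and fitted separately with limma it gave 0 genes and 1541 at an unadjusted p under 0.05. It too mixes the arms of each line, so the 0 does not show that the replicate number has no effect.

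The first pattern is that the arrays labelled PL45 resemble those of MiaPaca2. The same RNA on both sets is argued against by 11 genes that differed at least 4-fold between their control arrays by limma, DKK1, CTSC and SCG2 first, 7 of them detected on every control array of both. Their control arrays differed in 2.70% as many genes as those of PL45 and Capan-2 (168 genes, which dropped to 99 with the authors' values and 35 without PL45 control replicate 2), so a candidate explanation is cultures of 1 line under both names, grown apart. Separate lines of like state stay open, and no test here parts them from that. No biological explanation was tested.

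The second pattern is that genes abundant in MiaPaca2 and PL45 were lower in Capan-2 knockdown than in Capan-2 control arrays, as for VIM, CD74 and EMP3. Signal passed between arrays is argued against by the reverse floor (the 1% quantile of the share of a level found on other arrays), at most 0.055% for Capan-2-abundant genes on MiaPaca2 or PL45 arrays, against 2.48% and 2.38% on the Capan-2 controls. A background difference is argued against by equally dim genes, with a median log2 fold change of 0.0218, against -0.40 for the 59 genes at least 16-fold higher in the other lines' controls than on all Capan-2 arrays. Since that choice uses the knockdown arrays, it was repeated afterwards with control arrays alone, which gave -0.01 for dim genes and -0.27 for 53 genes. A lower share of MiaPaca2-like cells or RNA may explain part. A first test, at the median share the called genes need, left it open, with 3 abundant genes under 1.90%, 0.5 of that share, where 5 would have excluded it, and tests per gene were added after that result. TMEM158 and SRGN lost 8.85% and 4.05% of their MiaPaca2 and PL45 level, more than the whole Capan-2 control level of 19 and 14 abundant genes, which argues against it as their whole cause. For SCG2 and HLA-DPA1 that count was 3, and for the other abundant genes 1 lay far under the floor (less than a fraction of 0.25 of it) and 13 of 14 under 5% were lower, so a lower share and a change within Capan-2 cells cannot be told apart there.

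The third pattern is that few genes were called in Capan-2. Noisier arrays are argued against by a spread between replicates 0.993 times that of the other lines. An exchange of 1 control and 1 knockdown array that hid a response like the other lines' is argued against. Replicates of an arm differed by at most 0.025 of that response. A response of another kind would not be seen by that comparison. Capan-2 arrays of the same arm correlated at 0.990 and 0.991, within the range of different arms (0.986 to 0.993). A weaker knockdown of SLC16A3 may be the cause, and cannot be told apart from a weaker response of the line, since 0 probes are named for SLC16A3.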

How the results depend on the processing

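The crossed pairing, the set without genes at least 4-fold higher in the other lines, fits without the PL45 arrays and leaving out arrays for lists, similarity and control comparisons were chosen after seeing the data. The SLC16A3 alternatives were not run, since no probe is named for it. Signal over background limits dim genes, and the causes of the changes below were not tested except where fewer arrays or genes were used.

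Of 314 called values of named genes, 140 passed under every setting, 174 were lost under at least 1 and 0 reversed, most of those lost to fewer arrays or to the authors' values (65 lost). The similarity of MiaPaca2 and PL45 was r = 0.78 with no background correction, 0.60 with the authors' values and 0.79 with the strict filter, and ran from 0.60 to 0.74 leaving out 1 array. With Capan-2 it ran from 0.01 to 0.16 for MiaPaca2 and 0.08 to 0.17 for PL45. BSG, not called, reversed to 0.11 without the MiaPaca2 arrays and, leaving out 1 array, gave values from -0.12 to 0.10.

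Without the MiaPaca2 arrays 566 genes passed for the mean of 3 lines and without the PL45 arrays 544, against 2034. With the authors' values 816 passed in MiaPaca2, 832 in PL45, 9 in Capan-2, 47 in the F test and 99 between MiaPaca2 and PL45 controls, and 0 lists in Capan-2 (limma and camera, 9 lists at an unadjusted p under 0.05). Median scaling gave 835 in PL45, and its own 4 arrays alone 734. In Capan-2 the 5 calls became 0 with no background correction (766 at an unadjusted p under 0.05), 8 with no filter or with array weights, 3 with the strict filter, 12 with all probes, 9 with the mean of probes, 10 with trend and robust variance, 15 with its own 4 arrays and 1 without the genes 4-fold higher in the other lines.

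The replicate number, which also follows the position on the slide, was not treated as a pairing. Deviations of arrays with the same number correlated over 0.1 in 11 of 15 pairs of groups (-0.18 to 0.51). The 4 exceptions all involve Capan-2 control replicate 1, and the 10 pairs without it ran from 0.28 to 0.51. A block on the number gave 2156 genes in MiaPaca2, 2008 in PL45, 21 in Capan-2 and 640 in the F test. A block within lines gave 1970 in MiaPaca2, 15 in Capan-2 and 486 in the F test, and the crossed Capan-2 pairing gave 10 there.

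With no filter 11 lists passed for the mean and 9 in MiaPaca2, and with no background correction 5 in Capan-2. An estimated correlation gave 0 lists in each contrast, against 5, 4, 3 and 10 with the preset one (4, 4, 3 and 2 at an unadjusted p under 0.05), and fry gave 9 for the mean, 8 in MiaPaca2, 0 in Capan-2 (5 unadjusted) and 16 in PL45.

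Leaving out 1 array, which assumes that the lone sample varies like the other groups, gave 493 to 1314 genes in MiaPaca2, 639 to 1313 in PL45, 1 to 5 in Capan-2, 31 to 209 in the F test and 35 to 155 between MiaPaca2 and PL45 controls. The epithelial list was lost for the mean without PL45 knockdown replicate 1 (0.0687), MiaPaca2 control replicate 1 (0.0543), Capan-2 control replicate 2 (0.082) or Capan-2 knockdown replicate 2 (0.104). Lists ranged from 4 to 9 for the mean, 2 to 6 in MiaPaca2 and 4 to 12 in PL45.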

Other observations

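The families below were chosen after their values were seen. Small Cajal body RNAs, which guide modification of spliceosomal RNA, were mostly lower, with 9 of 17 lower by limma in the mean of 3 lines, 14 of 17 negative and a median log2 fold change of -0.66 (camera adjusted p = 9.19e-09, adjusted p = 0.125 with an estimated correlation). SCARNA8 led at -1.79, with SCARNA18 at -1.65 and SCARNA14 at -1.30. The median was -1.01 in MiaPaca2, -0.60 in PL45 and -0.09 in Capan-2 (camera adjusted p = 0.134 there, adjusted p = 0.591 with an estimated correlation), and stayed negative under the 4 other scalings, but with no background correction it shrank to -0.24 for the mean and -0.27 in MiaPaca2. In Capan-2, SCARNA23 was detected on 1 of 4 arrays and SCARNA8 had a control log2 level of 4.625, so low levels limit the falls that could be seen there. H/ACA small nucleolar RNAs, a related class, had 7 of 69 higher and 8 lower, and C/D small nucleolar RNAs were mostly higher among those that passed, with 11 of 71 higher and 2 lower (camera higher, adjusted p = 0.0115, adjusted p = 0.264 with an estimated correlation). The C/D median was 0.31 in MiaPaca2 (camera adjusted p = 4.09e-06, adjusted p = 0.188 with an estimated correlation). It was 0.07 in PL45 (camera adjusted p = 0.136, adjusted p = 0.501 with an estimated correlation) and -0.05 in Capan-2. MiaPaca2 and PL45 differed by camera with the preset correlation only (adjusted p = 0.000297, adjusted p = 0.322 with an estimated correlation). Under median scaling their medians were 0.149 and 0.116. The median for the mean dropped from 0.10 to 0.03 with no background correction.

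MHC class II genes, which present peptides to T cells, had 8 of 9 lower by limma, with a median of -0.61 (camera adjusted p = 7.89e-08, adjusted p = 0.125 with an estimated correlation). HLA-DPA1 and HLA-DMA fell by 1.09 and 0.94. In MiaPaca2 and in PL45 4 of 9 were lower by limma, and in Capan-2 1, HLA-DPA1. The Capan-2 median was -0.40 (camera adjusted p = 7.74e-07, adjusted p = 0.16 with an estimated correlation), but HLA-DPA1 and HLA-DRA are far more abundant in the other lines. For HLA-DPA1 a change within Capan-2 cells cannot be told apart from a lower share of MiaPaca2-like cells or RNA. Histone genes split, with 5 of 61 higher and 18 lower for the mean (camera lower, adjusted p = 0.000675, adjusted p = 0.382 with an estimated correlation). PL45 had 3 higher and 20 lower (camera lower, adjusted p = 1.44e-07, adjusted p = 0.31 with an estimated correlation) and MiaPaca2 6 higher and 3 lower (camera adjusted p = 0.887, adjusted p = 0.95 with an estimated correlation). As a family they differed between these lines by camera with the preset correlation only (adjusted p = 6.12e-16, adjusted p = 0.322 with an estimated correlation). H2BC12, H2AC6 and H2BC21 rose by 1.27, 0.76 and 0.75, while H3C12, H2BC6 and H3C3 fell by 1.29, 1.26 and 1.03.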
